A study of Hynobius leechii and Hynobius unisacculus and Hynobius quelpaertensis with 23 samples.

How the data were processed

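The study sequenced polyadenylated RNA of liver, intestine and skin from wild-caught adult Hynobius salamanders on an Illumina platform, after extraction with Trizol and Direct-Zol columns, per the labels' protocols. The extraction protocol speaks of embryos, while every sample is labelled as adult tissue. Per the submitters' processing notes the reads were handled with BWA and SAMtools, without a version, a genome build or a counting rule. Raw read counts were deposited by the authors in 6 tables, 1 per lineage, with 1 row per gene symbol and assembled sequence and 1 column per animal and tissue, per the file headers. The values were whole numbers, and no symbol had more than 1 row in a table. The symbols of the tables were taken as deposited, since no sequences or transcript lengths were used here, so whether a symbol stands for the same stretch of a gene in each table could not be checked. A row without a gene name, at most 0.169% of a library, was left out. The identifier beside the symbol was the same in every row of the QU table.

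Samples were assigned to lineage, tissue and animal from their titles, which match the column names of the tables. The description of 18 of the 23 samples names another lineage's table, and that of 5 names their own, and the title was used. No column was left unmapped. The counts of the 6 tables were joined by symbol, which gave 2252 genes found in all of them out of 13514 symbols, of which 1899 were in 1 table only. Total counts per library were 1703075 to 19281948, and 591087 to 5785558 on the shared genes. Counts of 0 were given a floor of 3 counts per library, which covers counting error only, and takes each count as a separate read. In libraries whose low counts were mostly even this need not hold, and the floor may be too low there.

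Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled with TMM factors on the shared genes, and quasi-likelihood models were fitted with glmQLFit (robust). Tissues were compared in a model of lineage plus tissue over all 23 libraries, with 5 intestines, 3 skins and 15 livers. Livers were compared between the 6 lineages by an F test and by contrasts in a model of lineage over the 15 livers, with each other species set against the equal-weight mean of HC1, HC3 and LE. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and genes at an adjusted p under 0.05 were called. The SE of a log2 fold change was its size divided by the square root of its F value. CPM are counts per 1000000 counts on the shared genes after scaling, unless a whole-table sum is named. In the report, CPM of tissue comparisons come from the fit over 23 libraries and those of lineage comparisons from the fit over 15 livers.

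Gene lists were tested with camera (limma 3.58.1) on voom values with an inter-gene correlation of 0.01 and again with an estimated correlation. This test sets a list against the other genes of the comparison, so its direction is relative to those genes. There were 33 lists of symbols, and those with 5 or more measured members in a comparison were tested and adjusted together. Lists with fewer members in the joined tables were not tested there. Members were also adjusted over the list alone. Named genes of a tissue comparison were the 10 largest and 10 smallest log2 fold changes among genes that were called, changed by at least 1 on the log2 scale, had the same sign in every animal with both tissues and reached 10 CPM in the higher tissue. For lineage contrasts the libraries of the sides had to be without overlap in place of the pairs, and 5 each way were named. For the F test the 10 genes with the smallest p and a mean of at least 10 CPM were named. From a list, up to 4 members with the highest CPM were to be named, and others are named where they were called. Some genes named by these rules are counted but not described. These comparisons, lists, naming rules and the alternatives below were chosen before the data were examined, except where stated.

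The alternatives were median-of-ratios size factors in the same fit, DESeq2 1.42.0, no filter, a stricter filter of 5 CPM in 3 libraries, the animal as a block in place of lineage, animals with both tissues only, each intestine or skin left out in turn in the tissue comparisons and each liver of the lineages compared in the others, and the genes of only the tables compared. Chosen after seeing the data were a term for library type, the fit without the 6 odd-count livers, whole-table library sizes and each table on its own. Library type was set from the share of odd values among counts under 20, with 0.3 as the limit. The pairing of tissues by animal was taken from the labels. Residuals of the fit could not test it, since the fit itself draws libraries of a lineage towards negative correlation and the liver of every pair had odd low counts. No correction for transcript length was made.

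The design was tested on simulated data with 200 changed genes in 4 fold sizes. For intestine against liver the share of changed genes called was 0% at a log2 fold change of 1, 18% at 2, 72% at 4 and 86% at 6. For skin against liver it was 0%, 6%, 30% and 70% at the same sizes, and for intestine against skin 0%, 0%, 24% and 48%. For HC1 against LE it was 0%, 0%, 6% and 36%, and for H. yangi against H. leechii 0%, 4%, 30% and 46%. Among unchanged genes, 4 of 2052 were called for intestine against liver, 2 of 2052 for skin against liver and 0 in the other simulated comparisons. A change of 4 on the log2 scale was thus mostly called for intestine against liver only, and a change of 6 was mostly missed in the last 3 of these comparisons. The simulated counts were drawn independently, without a shift of the odd-count livers or a link between tissues of an animal. The numbers of unchanged genes called therefore do not cover false calls from such structure.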

Results

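Polyadenylated RNA was sequenced from 23 tissue libraries of 15 untreated, wild-caught adult salamanders of the genus Hynobius in Korea. The animals fell into 6 lineages of 4 species. HC1, HC3 and LE were lineages of H. leechii, QU was H. quelpaertensis, UN was H. unisacculus and YA was H. yangi. Liver was taken from all 15 animals, with 3 livers in each H. leechii lineage and 2 in each other species. Intestine was taken from 5 of these animals, 1 each in HC1, LE, QU, UN and YA, and skin from 3, 1 each in HC1, HC3 and UN, so that 6 animals gave more than 1 tissue. The total count per library was 8672566 to 19281948 in liver, 1703075 to 3390245 in intestine and 2552636 to 4628175 in skin. Each lineage had its own count table, with 7111 to 10077 named genes, and 2252 of the 13514 symbols were found in all 6 tables. The counts on these shared genes, to which the joined comparisons were limited, were 20.8% to 43.3% of a library's total.

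The livers came in sets that differed in how their low counts were distributed. In 6 livers, the liver of each animal that gave more than 1 tissue, 43.0% to 51.4% of the counts from 1 to 19 were odd numbers. The other 17 libraries, 9 livers among them, had 11.3% to 22.5% odd values. The ribosomal protein gene RPS26 stood at 0 in all 6 odd-count livers, against a mean of 469 CPM (counts per 1000000 counts) in the 9 others, at least 723-fold lower with a floor of 3 counts per library. AHNAK was at 0 in the same 6 livers and at 26.7 CPM in the 9 others, at least 41.2-fold lower. Of 2252 genes in a fit with library type beside lineage and tissue, 58 were lower and 0 higher in the odd-count livers (edgeR, Benjamini-Hochberg), with 498 at an unadjusted p under 0.05. Rows at 0 made up 24.3% to 40.8% of the table in the odd-count livers, although their totals were 15103944 to 19281948 counts, against 8672566 to 16013480 in the 9 even-count livers, and in each table the odd-count liver had the most counts.

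**Figure D1:**
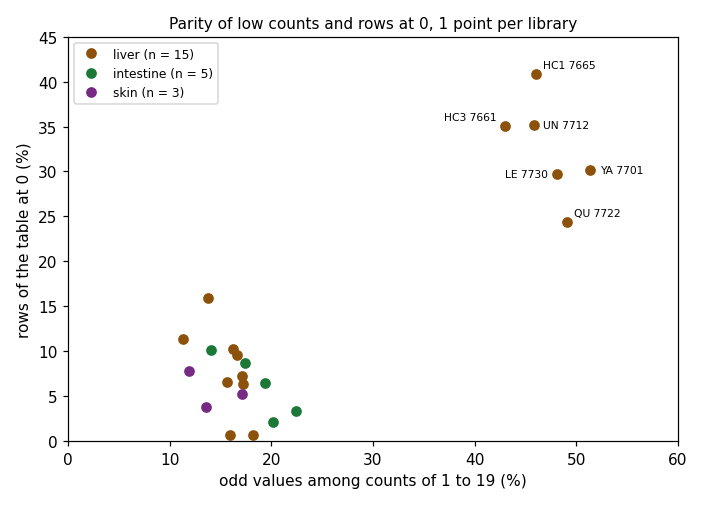
Share of odd values among counts of 1 to 19 (horizontal axis, %) and share of the table's rows at 0 (vertical axis, %), with 1 point per library and liver, intestine and skin in separate colours. The 6 labelled livers lie at 43.0% to 51.4% odd values and 24.3% to 40.8% rows at 0, and the 17 other libraries at 11.3% to 22.5% and 0.654% to 15.9%.

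Intestine was compared with liver to ask which transcripts separated gut from liver across the lineages. The gene for the secreted gel-forming mucin of goblet cells, MUC2, rose most among the named genes, from 6.57 ± 8.33 CPM (SD, n = 15) in liver to 28062 ± 10172 CPM (SD, n = 5) in intestine, a log2 fold change of 13.85 ± 1.44 (SE, adjusted p = 8.77e-06). In the livers of the same 5 animals it was at 0 counts, so with a floor of 3 counts its fold within an animal was at least 27579 to 81226. All 5 were odd-count livers, in which more rows stood at 0, and the floor covers counting error only. The bound thus need not hold against the even-count livers. FCGBP, another protein of intestinal mucus, rose by 6.38 ± 1.19 (adjusted p = 0.00322), from 50.3 to 2911 CPM. Smooth muscle myosin MYH11 rose by 5.42 ± 1.02 (adjusted p = 0.00333), from 309 to 4881 CPM. The secreted liver protein AMBP fell by 11.44 ± 1.26 (adjusted p = 1.46e-05), from 28397 ± 18436 CPM in liver to 6.08 ± 3.45 CPM in intestine. Coagulation factor F9 had a log2 fold change of -9.64 ± 0.93 (adjusted p = 3.11e-06), the canalicular bile salt pump ABCB11 of -8.03 ± 0.72 (adjusted p = 1.84e-06) and the tryptophan-degrading enzyme TDO2 of -7.19 ± 0.90 (adjusted p = 5.41e-05).

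The remaining named genes spanned several functions. ATP1B2, a subunit of the sodium pump, rose by 7.62 (adjusted p = 0.0108) and the mitochondrial fusion gene MFN2 by 6.65 ± 1.60 (adjusted p = 0.0164). Rows with the symbols of the retroelement-derived genes NYNRIN and RTL1 rose by 5.44 ± 1.48 and 5.12 ± 1.37, with adjusted p of 0.0285 and 0.0258. With library type as a term their adjusted p were 0.172 and 0.186. BCAS1 rose by 4.85 ± 0.89 (adjusted p = 0.00308). PPP1R14C rose by 4.84 ± 0.96 (adjusted p = 0.00492), and by 3.66 without the YA intestine (adjusted p = 0.0259). Among genes that fell, PLEK and CXCR2, transcripts of blood and immune cells, had log2 fold changes of -4.96 ± 0.59 (adjusted p = 2.89e-05) and -4.56 ± 0.93 (adjusted p = 0.00555). CXCR2 was at 0 counts in the HC1, QU, UN and YA intestines. With a floor of 3 counts its fall was at least 5.31-fold in HC1, 3.99-fold in UN and 6.32-fold in YA. These bounds take each count as a separate read, which is in doubt as low counts of the intestines were mostly even. In QU the bound of 0.709 showed no fall. HGFAC, BMP1, HHEX and the mitochondrial carrier SLC25A33 fell with log2 fold changes of -5.59, -4.27, -4.24 and -4.14 (SE 1.24, 1.11, 1.04 and 0.94). With the animal as a block, MFN2, PPP1R14C, HGFAC, BMP1, HHEX and SLC25A33 had adjusted p of 0.101, 0.0993, 0.0593, 0.152, 0.0852 and 0.0503, and the other 14 named genes kept their call. With the block and only the animals with both tissues none of the 20 did, and without the LE intestine 14 of 20 did.

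Functional groups, fixed beforehand, moved with these genes. Of 12 measured hepatocyte secreted proteins, 0 rose and 2 fell, AMBP and F9, with 2 also when adjusted over the list alone, and the group's median log2 fold change was -2.42 (camera adjusted p = 9.63e-15, and adjusted p = 0.00447 with an estimated correlation). The abundant members APOB and HPX did not pass, with 0.83 ± 1.58 (adjusted p = 0.775) and -0.65 ± 1.46 (adjusted p = 0.816), although the mean of APOB was 3904 CPM in intestine and 37947 CPM in liver. Of 8 amino acid and urea cycle enzymes, TDO2 alone fell, 1 of 8 also adjusted over the list alone, while OTC stood at -2.12 ± 1.20 (adjusted p = 0.283) (group adjusted p = 6.36e-08, and adjusted p = 0.0130 with an estimated correlation). In bile acid synthesis and transport, 2 of 6 members fell over all genes and over the list alone, ABCB11 and the basolateral transporter SLC51A (-5.96 ± 1.65, adjusted p = 0.0312), and 4 had positive values, so that the median of 0.46 was positive while the mean of -1.45 and the test were negative (adjusted p = 0.00803, but adjusted p = 0.155 with an estimated correlation). Among 6 iron and heme genes, HMOX1 fell with a log2 fold change of -3.14 ± 0.78 (adjusted p = 0.0189), the 1 call also adjusted over the list alone (group adjusted p = 0.00171, and 0.0750 with an estimated correlation). RPL3 was the 1 of 11 ribosomal protein genes that fell, at -2.35 ± 0.53 (adjusted p = 0.0109), with 2 adjusted over the list alone and RPL21 at 0.72 ± 1.08 (group adjusted p = 0.00152, and 0.167 with an estimated correlation).

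Epithelial and contractile groups were higher in intestine. Of 5 smooth muscle markers, MYH11 and the actin-binding CNN1 rose, 2 also adjusted over the list alone, CNN1 from 69.7 to 939 CPM with a log2 fold change of 4.23 ± 0.54, and all 5 were positive (group adjusted p = 0.00252, but 0.155 with an estimated correlation). Of 11 keratinocyte markers, 3 shared by other epithelia rose over all genes and over the list alone, the desmosomal genes DSP (3.96 ± 1.01) and DSC2 (3.83 ± 0.95) among them, and 10 were positive, with KRT5 at 1.19 ± 1.15 (group adjusted p = 0.00252, and 0.160 with an estimated correlation). Over the whole tables keratinocyte markers summed to 27574 CPM in the HC1 intestine and 2446 to 5259 CPM in the 4 others. Only 4 enterocyte and goblet cell markers were in all 6 tables, too few for a group test, of which MUC2 and FCGBP rose while HNF4G and USH1C did not pass. In the 5 tables with both tissues, 6 were measured and 4 rose, with the cadherin CDH17 rising from 59.1 to 4856 CPM (adjusted p = 0.00133) and the microvillus protein PLS1 from 27.1 to 939 CPM (adjusted p = 0.00344) (group adjusted p = 4.65e-06, but 0.105 with an estimated correlation). The carbonic anhydrase CA2 rose by 3.93 ± 0.65, from 172 to 2493 CPM, as 1 of 4 ionocyte markers, and JUND rose by 2.22 ± 0.67 as 1 of 4 immediate early genes. Of 4 erythroid markers, the anion exchanger SLC4A1 rose by 3.53 ± 1.01 while the heme enzyme UROD fell, at -1.54 ± 0.47.

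Some groups passed as a whole with few or no called members. Complement (5 measured, 0 called), heat shock and protein folding (7, 0 called) and antioxidant defence (5, 0 called over all genes, and 1 higher adjusted over the list alone) had camera adjusted p of 0.00735, 0.00382 and 0.0298 towards lower values, which became 0.155, 0.155 and 0.210 with an estimated correlation. Their named members included C6 at 1.66 ± 1.62, HSPD1 at -0.92 ± 0.45, and SOD1 at 5.59 ± 1.90 (adjusted p = 0.0742). The mean was positive in complement and antioxidant defence, at 0.06 and 0.84, while the medians of -0.84 and -0.67 and the tests were negative. As the tests were made against the other genes, they do not show that these groups were lower in intestine than in liver. Oxidative phosphorylation, with NDUFA8 at -1.49 ± 0.44 as the 1 of 6 that fell over all genes and over the list alone, had an adjusted p of 0.0241 (0.220 with an estimated correlation). Fatty acid oxidation did not pass (adjusted p = 0.606, 1 of 7 higher over all genes and over the list alone, CPT2 at 2.41 ± 0.65), with a negative test and a positive median of 0.95 and mean of 0.65. Leukocyte markers did not pass (0.0649), although CORO1A fell, at -2.26 ± 0.53, and 1 rose and 1 fell adjusted over the list alone. Fatty acid and cholesterol synthesis (8 genes, adjusted p = 0.432, with a positive median of 0.14 beside a negative test) held no call, and xenobiotic metabolism (5 genes) did not pass either.

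Over all 2252 genes, 190 differed between intestine and liver, 140 higher and 50 lower, with 557 at an unadjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). The median log2 fold change of all genes was 0.71, and with median-of-ratios scaling it was 1.10 with 336 higher and 44 lower. Without the 6 odd-count livers it was 0.17, with 211 higher and 150 lower, and with library type as a term it was 0.34, with 60 higher and 61 lower. With the animal as a block 93 were higher and 6 lower, 43 of them among the 190. With the block and only the animals with both tissues 0 genes passed in edgeR, 450 at an unadjusted p under 0.05, while DESeq2 without a block gave 839. Leaving out the intestine of LE, UN, HC1 or QU gave 82, 101, 103 or 123 genes.

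**Figure D2:**
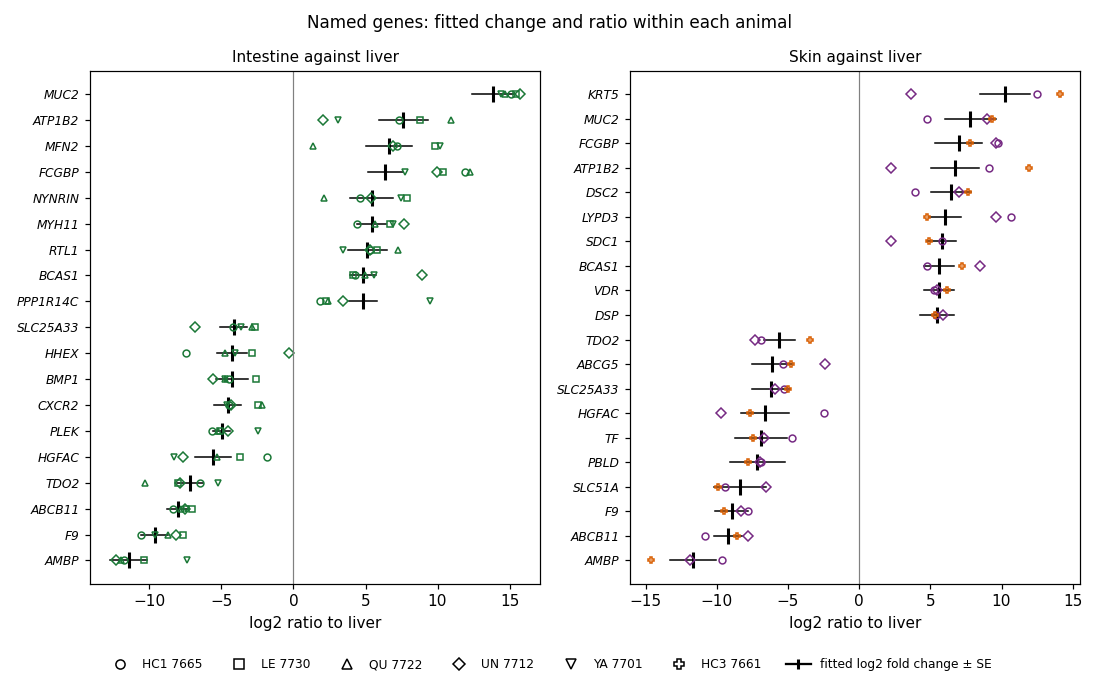
Log2 ratio to the liver of the same animal (horizontal axis) for named genes of the intestine and skin comparisons, 1 open symbol per animal, with the fitted log2 fold change (tick) and its SE (line). MUC2 had 0 counts in the 5 livers paired with an intestine and KRT5 in the UN liver paired with a skin, so the prior count sets these ratios. Some intestine ratios of ATP1B2, MFN2, FCGBP, NYNRIN, RTL1, BCAS1, PPP1R14C, F9, CXCR2 and HHEX also had 0 counts on 1 side. For skin this held for some ratios of MUC2, ATP1B2, DSC2, LYPD3, SDC1, BCAS1, VDR, DSP, HGFAC and ABCG5. The size of all of these ratios depends on the prior count as well.

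Skin was compared with liver for the same question at the body surface. The basal keratin KRT5 rose most among the named genes, from 147 ± 238 CPM (SD, n = 15) in liver to 10625 ± 12958 CPM (SD, n = 3) in skin, a log2 fold change of 10.25 ± 1.76 (adjusted p = 0.00262). In the UN skin it was at 8.69 CPM (12 counts), at least 17.2-fold above its liver with a floor of 3 counts. The desmosomal genes DSC2 and DSP rose by 6.46 and 5.49 (both adjusted p = 0.0134), DSP averaging 20993 ± 18165 CPM, with 30.7 CPM in the HC3 skin. LYPD3 and the syndecan SDC1 rose by 6.05 ± 1.13 (adjusted p = 0.00446) and 5.79 ± 1.04 (adjusted p = 0.00416), and the vitamin D receptor VDR by 5.58 ± 1.06 (adjusted p = 0.00473), to 64.2 CPM. The mucin MUC2 was also higher in skin than in liver, by 7.79 ± 1.78 (adjusted p = 0.0168) at 4475 ± 7398 CPM (SD, n = 3). It was at 20.4 CPM in the HC1 skin and 389 CPM in the UN skin, so its mean came mostly from the HC3 skin. FCGBP was higher by 6.99 ± 1.64 (adjusted p = 0.0195) at 8130.3 ± 10627 CPM. ATP1B2 rose by 6.73 ± 1.69 (adjusted p = 0.0268) and BCAS1 by 5.60 ± 1.03 (adjusted p = 0.00433). With library type as a term FCGBP, DSC2 and DSP had adjusted p of 0.0940, 0.0503 and 0.0626.

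Among the genes lower in skin, AMBP fell from 28397 CPM in liver to 11.1 CPM in skin, with a log2 fold change of -11.68 ± 1.62 (adjusted p = 0.0003). ABCB11, F9 and TDO2 had values of -9.22 ± 0.98, -8.97 ± 1.16 and -5.62 ± 1.09 (adjusted p = 3.04e-05, 0.000112 and 0.00524). SLC51A fell with -8.35 ± 1.83, the phenazine biosynthesis-like gene PBLD with -7.16 ± 1.93, the iron carrier TF with -6.88 ± 1.84, and HGFAC with -6.61 ± 1.71 (adjusted p = 0.0134, 0.0392, 0.0378 and 0.0320). SLC25A33 and the sterol transporter ABCG5 fell with -6.22 ± 1.35 and -6.12 ± 1.38 (adjusted p = 0.0132 and 0.0157). None of the 20 named genes, chosen among those with the same sign in the 3 animals, kept its call with the animal as a block, where the adjusted p lay between 0.0550 and 0.192. Leaving out the skin of HC3, UN or HC1 ended 12, 9 or 8 of the 20 calls.

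Keratinocyte markers were higher in skin as a group. All 11 measured members were positive, 5 rose over all genes and 8 adjusted over the list alone, and the median was 3.37 (camera adjusted p = 5.92e-11, and adjusted p = 0.00968 with an estimated correlation). The transglutaminase TGM1, a maker of the cornified envelope, rose by 4.93 ± 0.56, from 38.5 to 1943 CPM, while KRT6A stood at 0.45 ± 1.18. Hepatocyte secreted proteins fell as a group, 3 of 12 over all genes and 4 adjusted over the list alone, at a median of -4.76 (adjusted p = 1.9e-14, and 0.00389 with an estimated correlation), with HPX at -4.08 ± 2.05 among those that did not pass. Amino acid and urea cycle enzymes (1 of 8 lower on either count, TDO2) and bile acid genes (2 of 6 lower on either count, ABCB11 and SLC51A) had adjusted p of 1.27e-08 and 2.34e-05, and 0.00968 and 0.0197 with an estimated correlation. Smooth muscle markers were higher (adjusted p = 0.00729, but 0.145 with an estimated correlation), with CNN1 at 2.93 ± 0.64 as the 1 of 5 that rose and 2 adjusted over the list alone.

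Other groups passed only with the preset correlation. Complement, ribosomal proteins, oxidative phosphorylation, heat shock genes, iron handling, fatty acid oxidation and antioxidant defence had adjusted p of 0.00319, 0.000522, 0.00364, 0.00947, 0.00947, 0.0108 and 0.0200 towards lower values than the other genes. With an estimated correlation these were 0.0822, 0.145, 0.145, 0.145, 0.137, 0.145 and 0.157. TF was the 1 member of these groups called over all genes, and over the list alone 1 oxidative phosphorylation gene was lower, NDUFA8 at -2.02 ± 0.57 (adjusted p = 0.0513 over all genes). Antioxidant defence had a negative median and a positive mean of 0.28, with SOD1 at 5.11 ± 2.01. Leukocyte markers did not pass (adjusted p = 0.0664), although CORO1A fell, at -3.70 ± 0.73, and fatty acid and cholesterol synthesis (0.517) and xenobiotic metabolism (0.177) did not pass either.

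In the 3 tables with both skin and liver, 4780 genes could be tested, and 238 were higher and 76 lower in skin. Without the odd-count livers these were 299 and 153. Of 30 keratinocyte markers, 13 rose and 23 adjusted over the list alone, with the hemidesmosomal collagen COL17A1 at 9.08 ± 1.39 (583 against 0.732 CPM), the desmogleins DSG1 and DSG4 at 7.19 and 6.53, and EVPL at an adjusted p of 0.0285 (group adjusted p = 1.83e-16, but 0.0674 with an estimated correlation). Of 19 skeletal muscle markers, 4 rose and 10 adjusted over the list alone. The myosins MYH8 and MYH1 rose by 10.23 ± 1.14 (2501 against 2.35 CPM) and 7.80 ± 1.92, and the Z-disc genes ACTN2 and TCAP by 6.04 ± 1.12 and 8.05 ± 1.49 (group adjusted p = 4.7e-05, but 0.304 with an estimated correlation). Hepatocyte secreted proteins fell in 9 of 17, 10 adjusted over the list alone, with kininogen KNG1 at -12.38 ± 1.45, antithrombin SERPINC1 at -8.05 ± 0.93, and the retinol carrier RBP4 at -8.21 ± 1.10 (group adjusted p = 3.23e-20, and 0.0302 with an estimated correlation). Gluconeogenesis and glycogen genes fell in 2 of 11, 3 adjusted over the list alone, with GBE1 at -4.29 ± 0.71 (group adjusted p = 8.25e-05, and 0.0378 with an estimated correlation). Of 14 xenobiotic enzymes 2 fell, the microsomal MGST1 and CYP4B1, with -5.53 ± 0.95 and -4.17 ± 0.78. These members were picked for mention after their values were seen.

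Over the 2252 shared genes, 92 differed between skin and liver, 69 higher and 23 lower, with 406 at an unadjusted p under 0.05 (edgeR, Benjamini-Hochberg). The median log2 fold change was 0.60, and with median-of-ratios scaling it was 0.91 with 151 higher and 25 lower. Without the 6 odd-count livers it was 0.16, with 153 higher and 98 lower, and all 92 genes were among these. With the animal as a block 0 genes passed in edgeR, 439 at an unadjusted p under 0.05, while DESeq2 without a block gave 448, and with only the animals with both tissues it was also 0, with 285 at an unadjusted p under 0.05. Leaving out the skin of HC3, UN or HC1 gave 25, 44 or 58 genes.

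**Figure D3:**
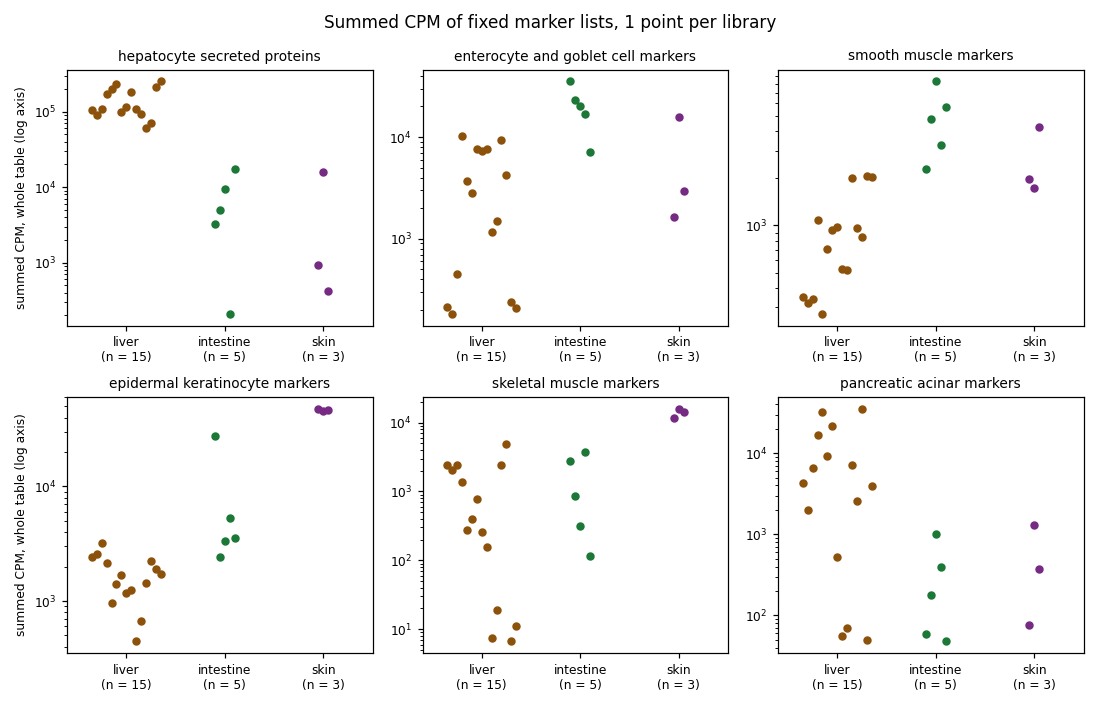
Summed CPM of the measured members of 6 fixed marker lists, each over the library's whole table (vertical axis, log scale), with 1 point per library for liver (n = 15), intestine (n = 5) and skin (n = 3). Keratinocyte markers lie between 46015 and 47910 CPM in skin and between 444 and 3224 CPM in liver, and acinar markers range from 49.2 to 35521 CPM among livers.

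Intestine and skin were compared to separate the lining of the gut from the covering of the body. TGM1 was lower in intestine, at 39.2 ± 42.9 CPM (SD, n = 5) against 1943 ± 393 CPM (SD, n = 3) in skin, with a log2 fold change of -4.42 ± 0.76 (adjusted p = 0.0287). The ratios within the 2 animals that gave both tissues were -4.47 and -4.20 on the log2 scale. KRT5 had a larger fitted difference, -9.06 ± 2.15, which did not pass (adjusted p = 0.299), at 331 CPM in intestine and 10625 CPM in skin. DSP stood at -1.52 ± 1.57 and MUC2 at 6.06 ± 2.27, and MUC2, at 28062 against 4475 CPM, did not pass either (adjusted p = 0.999). As a group the 11 keratinocyte markers were lower in intestine, 1 over all genes and 2 adjusted over the list alone, with a median of -1.52 (camera adjusted p = 1.28e-10, and adjusted p = 0.0221 with an estimated correlation). Fatty acid oxidation genes were positive in 7 of 7, with 0 called on either count, and bile acid genes had ABCC2 at 3.01 ± 2.10 (both groups adjusted p = 0.00194, but 0.0991 with an estimated correlation).

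TGM1 was the 1 gene of 2252 that passed, with 71 at an unadjusted p under 0.05 (edgeR, Benjamini-Hochberg), and DESeq2 called 40, of which 22 were higher and 18 lower. With the animal as a block its log2 fold change was -4.66 with an adjusted p of 0.413, and leaving out any 1 of the intestine and skin libraries other than the YA intestine gave 0 genes. Of 6595 genes in the 2 tables with both tissues 0 passed in edgeR, 137 at an unadjusted p under 0.05, while their enterocyte markers were positive in 20 of 23 (group adjusted p = 1.97e-08, but 0.212 with an estimated correlation).

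The livers were compared between lineages to ask how gene activity in 1 organ differed among the Korean Hynobius. Among the 10 genes with the smallest p, the elongation factor EEF2 averaged 49366 CPM in HC3 (n = 3) and 46602 CPM in UN (n = 2), and 25.3 to 108 CPM in the other 4 lineages (F test adjusted p = 5.03e-05). SLU7, a splicing factor, averaged 72440.1 CPM in QU and 206 to 313 CPM elsewhere, and the mitochondrial ribosomal gene MRPS23 37912 CPM in HC3 and 52.4 to 121 CPM elsewhere. IP6K2 reached 32178 CPM in UN against 213 to 427 CPM, ERGIC1 52028 CPM in YA against 436 to 616 CPM, ITM2B 25687 CPM in QU against 169 to 498 CPM, and ME2 14444 CPM in HC3 against 156 to 461 CPM. The ammonium transporter RHBG averaged 58151 CPM in HC3, 0 in UN and 689 to 1839 CPM in the other lineages. TMEM43 and RALA were at 0 in HC1, with their highest means in LE, 12758 CPM, and in QU, 10842 CPM. Over 2251 genes, 1473 differed among the 6 lineages, with 1593 at an unadjusted p under 0.05 (edgeR quasi-likelihood F test, Benjamini-Hochberg).

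Each lineage was read from its own table, so a difference between lineages was also a difference between tables. A row without counts in a table thus need not mean that the transcript was absent. The folds between lineages, lower bounds included, compare rows of different tables. Across the 2252 shared genes, livers of different tables had a median Spearman correlation of 0.176 (0.116 to 0.228, 93 pairs of livers), and livers of the same table a median of 0.912 (0.895 to 0.963, 12 pairs). Between livers of different H. leechii lineages the median was 0.184 (27 pairs), and between species 0.173 (66 pairs). Different tissues read from the same table had a median of 0.792 (22 pairs). These correlations run across genes, which are not independent replicates.

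Within H. leechii, HC1 was first compared with LE. The methyltransferase gene INMT averaged 25164 ± 11791 CPM (SD, n = 3) in HC1 and 0.610 CPM in LE, a log2 fold change of 15.43 ± 2.07 (adjusted p = 0.00126). RBP4 averaged 10183 ± 2431 CPM against 0.287 CPM (15.17 ± 1.94, adjusted p = 0.0012), and ISYNA1 13115 ± 17112 CPM against 0.287 CPM (15.54 ± 3.30, adjusted p = 0.00657). The ribosomal protein genes RPS19 and RPL23 were higher by 13.92 ± 2.40 and 13.30 ± 1.98, with adjusted p of 0.00276 and 0.00167. TMEM43 was at 0 in the 3 HC1 livers, at least 15611-fold lower than in LE, where the floor was 3 counts per library, and CPB2, a plasma carboxypeptidase, was at least 10154-fold lower. CAPG, RSL1D1 and SERPINF2 were at least 2823-fold, 1699-fold and 1648-fold lower. In total 645 genes differed, 283 higher and 362 lower in HC1, with 870 at an unadjusted p under 0.05, and no gene list passed (smallest adjusted p = 0.871). Of 11 ribosomal protein genes 3 were higher and 2 lower on either count, with RPLP1 at -13.38 ± 1.84 beside RPL7A at -0.07 ± 0.88. Hepatocyte secreted proteins split in the same way, 3 higher and 2 lower of 12, with 3 and 3 adjusted over the list alone.

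HC3 against LE gave 596 genes, 278 higher and 318 lower, with 833 at an unadjusted p under 0.05. Rows with the symbols of core liver genes were among those higher in HC3. Whether these rows hold the same stretch of a gene in both tables could not be checked. The urea cycle enzyme CPS1 averaged 68796 ± 31094 CPM in HC3 and 1.83 CPM in LE (15.24 ± 2.63, adjusted p = 0.00318) and the lipoprotein gene APOB 79996 ± 18497 against 2.15 CPM (15.22 ± 2.60, adjusted p = 0.00306). RBP4 and RPL23 were higher by 15.38 ± 1.95 and 14.40 ± 2.05. Lower in HC3 were the chaperone CALR (-14.56 ± 2.32), CPB2 (-14.44 ± 2.07), CLEC16A (-14.17 ± 3.01), the cytochrome P450 reductase POR (-13.67 ± 3.10) and COX4I1 (-12.86 ± 1.59), with adjusted p of 0.00253, 0.00288, 0.00743, 0.00945 and 0.00154. Of 8 amino acid and urea cycle enzymes 5 were higher on either count, CPS1 among them, and of 12 hepatocyte secreted proteins 5 were higher on either count, at a median of 2.10 (both camera adjusted p = 0.00099, but 0.789 with an estimated correlation). OTC and TDO2, of the same enzyme group, stood at -0.09 ± 1.64 and 0.69 ± 0.64. Without the liver of mms7660, mms7662, mms7728 or mms7729, 381, 391, 382 or 384 genes differed.

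HC1 against HC3 gave 610 genes, 296 higher and 314 lower, with 858 at an unadjusted p under 0.05. INMT was higher in HC1 by 15.07 ± 2.05, RPS19 by 14.40 ± 2.46, CALR by 13.37 ± 2.24, POR by 13.07 ± 3.04 and PGRMC1 by 12.98 ± 3.13, with adjusted p of 0.000958, 0.00228, 0.00206, 0.00938 and 0.0108. APOB averaged 0.632 CPM in HC1 and 79996 CPM in HC3 (-16.98 ± 2.73, adjusted p = 0.00163). The nucleolar gene NPM1 was at 0 in HC1, at least 10317-fold lower with the floor of 3 counts per library, and LIPC, CCT2 and SERPINF2 at least 2888-fold, 2524-fold and 2427-fold lower. Of the amino acid and urea cycle enzymes 5 of 8 were lower on either count, at a median of -8.54, and of the hepatocyte secreted proteins 4 of 12 on either count, at a median of -2.35 (both adjusted p = 0.00487, but 0.993 with an estimated correlation). These medians did not move with FTCD and SERPINF2, which were at 0 in HC1, set to their bounds. With scaling on the whole tables the median of all genes moved from -0.09 to 0.70, with 449 higher and 314 lower. The same scaling moved the median of HC3 against LE to -0.45 and that of HC1 against LE to 0.28.

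Each other species was compared with the mean of the 3 H. leechii lineages on the log scale, and for genes at 0 in the HC1 livers the levels are given in place of the fitted change, which then depends on the prior count. In QU, the amine oxidase gene ABP1 averaged 3232 ± 1719.9 CPM (SD, n = 2) against 0, 0.358 and 0.574 CPM in HC1, HC3 and LE (adjusted p = 0.00102), and NUDT2 18774 CPM against 165, 2.57 and 0.610 CPM (adjusted p = 0.000133). The endothelial scavenger receptor STAB2 averaged 31567 ± 35498 CPM, an SD above its mean, against 1.15, 2.57 and 778 CPM (adjusted p = 0.00185). The anticoagulant protein C gene PROC was higher by 11.12 ± 1.68. RALA averaged 10842 ± 11775 CPM against 0, 35.8 and 113 CPM in HC1, HC3 and LE (adjusted p = 5.12e-05). The mitochondrial chaperone HSPA9 was lower, at 0.381 against 1390.3 CPM (-11.88 ± 2.97, adjusted p = 0.0119), as were H2AFY2 (-11.23 ± 1.85), HNRNPCL1 (-10.76 ± 2.13), NOP58 (-10.60 ± 2.61) and DNAJA2 (-10.55 ± 2.12). All 6 oxidative phosphorylation genes were positive in QU, 4 were higher and 5 adjusted over the list alone, with UQCRC2 at 7.10 ± 1.04 and CYC1, at 0 in HC1, at 9429 CPM, although UQCRC2 averaged 952 CPM in QU and 831 CPM in LE (group median 3.81, adjusted p = 0.0469, but 0.901 with an estimated correlation). Over the highest H. leechii lineage, QU had 15.8 times as much CYC1. For NDUFA8, UQCRC1, UQCRC2, COX4I1 and COX7A2 this ratio was 1.05, 1.20, 1.15, 1.14 and 0.789. COX4I1 was near 0 in HC3 (0.358 CPM) and COX7A2 in LE (0.897 CPM). In total 620 genes differed, 479 higher and 141 lower, with 882 at an unadjusted p under 0.05. Of these, 210 higher and 96 lower genes met the naming rule, which asks for no overlap with the H. leechii livers. The p-values of the species contrasts rest on the spread of livers within a lineage. They leave out the spread between lineages. Leaving out the QU liver of mms7722 gave 366 genes, with HSPA9 and NOP58 no longer called (adjusted p = 0.0816 and 0.0578), and leaving out that of mmsX002 gave 410, 237 higher and 173 lower.

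In UN, the replication fork gene TIPIN averaged 675 ± 272 CPM (SD, n = 2) against 0, 0.358 and 0.287 CPM in HC1, HC3 and LE (adjusted p = 0.0011), and the fatty acid transporter SLC27A2 1196 ± 199 CPM against 0, 1.71 and 2.80 CPM (adjusted p = 0.00171). PPIB averaged 2043 CPM against 0, 1.49 and 26.7 CPM (adjusted p = 0.00345), and LNX2 and EIF2B2 were higher by 10.29 ± 1.35 and 9.86 ± 1.46. Lactate dehydrogenase LDHA was lower, at 0.328 against 5872 ± 1852 CPM (-14.17 ± 1.69, adjusted p = 0.000534). The protease inhibitor PZP and RHBG were at 0 in both UN livers, at least 8702-fold and 4241-fold lower than the log-scale mean of the 3 lineages with the floor of 3 counts per library, and at least 294-fold and 941-fold lower than the lineage with the least, HC3 and LE. HIPK3 and GCN1L1 were at least 1166-fold and 786-fold lower than the log-scale mean. Of 11 ribosomal protein genes, 2 were higher and 5 lower, with 2 and 6 adjusted over the list alone, RPSA at -12.89 ± 1.91 and RPS19 at 9.02 ± 1.28 among them, and the group did not pass (adjusted p = 0.146). RPS19 averaged 6878 CPM in UN, 9211 CPM in HC1, and 0.498 and 0.646 CPM in HC3 and LE. No list passed, the smallest adjusted p being 0.0574. In total 642 genes differed, 404 higher and 238 lower, with 919 at an unadjusted p under 0.05. Of these, 165 higher and 126 lower genes met the naming rule with its lack of overlap. The total was 383, 286 higher and 97 lower, without the liver of mms7712. Without the liver of mms7714 there were 239 higher and 299 lower, and the median of all genes moved from 0.02 to -0.60.

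In YA, PPIB was again higher, at 1605 ± 809 CPM (SD, n = 2) against 0, 1.49 and 26.7 CPM in HC1, HC3 and LE (adjusted p = 0.00567). The complement inhibitor SERPING1 averaged 8398 ± 5572 against 14.5 CPM (9.63 ± 1.37, adjusted p = 0.00143), and NACA, ENTPD5 and DEK were higher by 9.91 ± 1.60, 9.89 ± 1.51 and 9.77 ± 1.06. SLC51A was lower, at 0.297 against 2947 ± 1123 CPM (-13.25 ± 1.79, adjusted p = 0.00108), and the iron carrier TF averaged 1.33 against 4355 CPM (-11.53 ± 2.18, adjusted p = 0.0049). NOP58, AADAC and the stress factor ATF4 were lower, at -12.89 ± 2.86, -11.82 ± 1.73 and -11.76 ± 2.15. Of 12 hepatocyte secreted proteins 3 were higher and 5 lower, with 3 and 6 adjusted over the list alone, APOB at 10.30 ± 1.37 and CP at -11.15 ± 2.13 among them, and the group did not pass (adjusted p = 0.793). APOB averaged 59155.5 CPM in YA, 79996 CPM in HC3, and 0.632 and 2.15 CPM in HC1 and LE. Across the lists the smallest adjusted p was 0.108. In total 582 genes differed, 378 higher and 204 lower, with 873 at an unadjusted p under 0.05. Of these, 154 higher and 139 lower genes met the naming rule with its lack of overlap. Without the liver of mms7701 the count was 354, 288 higher and 66 lower, with NOP58 no longer called (adjusted p = 0.0522), and without that of mms7700 it was 464, 226 higher and 238 lower, with a median of all genes of -0.39. With library type as a term it was 902. Median-of-ratios scaling moved the median of all genes from -0.12 to 0.26, with 545 higher and 229 lower.

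The intestines of H. leechii and of the other species were compared to ask whether the step from liver to intestine differed between them, with 2 animals against 3. No gene passed for the difference in edgeR, with 55 of 2252 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998, and no other tool was run for it. The log2 ratios of intestine to liver within an animal correlated between animals of different tables at r = 0.222 to 0.333 (10 pairs of animals), and those of skin to liver at r = 0.336 to 0.405 (3 pairs), across genes, which are not independent replicates.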

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

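All tests in this part were chosen after the results were seen, except the splits made without the 6 odd-count livers. In 53 groups of 5 values (20 named genes, 30 gene lists and 3 library measures of the intestines), 2 held a value set far apart from the other 4, while chance gives such a value in about 1 of 20 groups. The log2 ratio of intestine to liver of PPP1R14C was 9.49 in the YA animal mms7701 and 1.85 to 3.41 in the other 4 animals. Without that intestine its fitted log2 fold change was 3.66 (adjusted p = 0.0259) in place of 4.84. The summed pigment cell markers had a ratio of -3.06 in the HC1 animal mms7665 and 0.86 to 2.38 in the other 4 animals. This came from PMEL, which stood at 22279 CPM in the liver of mms7665, against 1819.7 and 2247 CPM in the other HC1 livers. No explanation was tested for either value.

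A further signal lay in genes that the comparisons of the report did not use, the digestive enzymes of pancreatic acinar cells, which were far above their floor in some livers. Their summed CPM over the whole table was 6592 in the HC1 liver of mms7666, 32023 in the HC3 liver of mms7661 and 21449 in the LE liver of mms7728. It was 7194 in the QU liver of mmsX002, 35521 in the UN liver of mms7714 and 3899.8 in the YA liver of mms7701. The lowest liver of the same tables had 2017, 9148, 55.2, 69.3, 2569.5 and 49.2 CPM in that order. The median ratio of highest to lowest liver was 46.6 over the 6 tables (3.27 to 389), the largest of the 33 gene lists.

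Pancreatic tissue taken with some liver pieces is a candidate explanation for the acinar transcripts. In the liver with the most trypsin transcript, 97.9% of the other acinar members (46 of 47) were higher than in the liver with the least, against 44.8% of the genes outside the list. PRSS1 stood at 13950 against 138 CPM in UN, 10995 against 18.2 CPM in LE and 8715 against 10.6 CPM in HC3, where CTRC still had 8972 CPM in the liver with the least trypsin. Of the 25 genes on the list 0 were on another list, and 1 to 7 of those measured reached 10 CPM in the liver with the least trypsin. Library type was argued against, as the odd-count liver had the highest sum in 2 tables and the lowest in 4, and expression of these genes by liver cells themselves, for which the design gave no group, was not tested.

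The 6 livers with odd low counts had more genes at 0 than the other livers. Lower depth was argued against, since the odd-count liver had both the most counts and the most genes at 0 in 6 of 6 tables, and so was a trait shared by all tissues of these animals, since 0 of their 8 intestine and skin libraries had odd low counts. Genes missed together in a library or counting batch may explain part of the zeros. Among 624 genes with 10 or more counts in every other liver, 77 were at 0 in 3 or more of the 6 livers, against a median of 34 in 10000 shuffles of genes within libraries. Genes with few counts are at 0 more often in any library, and with shuffles only among genes of like level in the other livers of the table the median was 58 and the highest value 76 (permutation p = 0.0001, the smallest they can give). Much of the overlap thus went with low level, and the rest does not single out a batch from another property of the genes. Of these 624 genes, 2 were at 0 in all 6 livers. Whether these livers were prepared or counted apart was not tested, and as they are the livers of every animal with more than 1 tissue, a comparison within an animal set an even-count intestine or skin against an odd-count liver.

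Liver levels of the same symbol differed widely between tables. The assembled sequence that carries a symbol in each table is a candidate cause, since the difference between HC1 and LE in intestine followed that in liver across genes (r = 0.808, and 0.801 to 0.844 over the 10 pairs of tables with both tissues). Divergence between species was argued against as the main cause, as the median correlation of liver levels within H. leechii exceeded that between species by 0.0114. A smaller part from divergence could not be judged, since the correlation between tables was already low within H. leechii. A heritable difference in expression shared by the tissues of a lineage would also give a high correlation between tissues. For some ribosomal protein genes, whose products every liver needs, the levels argue against it. RPS19 averaged 9211 CPM in HC1 livers, and 0.498 and 0.646 CPM in HC3 and LE. RPL23 averaged 0.610 CPM in LE, RPLP1 0.518 CPM in HC1 and RPSA 0.985 CPM in UN. RPL3, RPL7A, RPS15 and RPS26 did not fall as low in any lineage. For the other genes a heritable difference stays open and was not tested.

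Other splits of the same libraries were compared with the real ones. For intestine against liver 1 of 100 splits, the real one, gave a count as large, with 190 genes and 75 as the highest other. That other split set 5 odd-count livers apart. The splits were drawn from 15504 possible ones and ignored lineage and animal. Mixed splits also left the tissue difference in the residual spread, which lowers their counts. They show that the tissue labels mattered and cannot exclude chance for the genes called. For skin against liver 4 of 100 splits that ignore lineage and animal gave as many as the real 92, and the 3 others, with 181, 118 and 105 genes, each set 3 odd-count livers apart, which points to a structure of the livers and not of the tissues. Without the 6 odd-count livers, 1 of 100 splits for intestine (361 genes, highest other 1) and 1 of 99 for skin (251 genes, highest other 1) gave a count as large. It was the real one in each case, and these splits have the same limit. For intestine against skin 8 of 56 splits gave as many as the real 1 gene, with 3 as the highest other, so chance cannot be excluded. Swapping tissues within animals gave 61 genes with all 5 intestines swapped and at most 9 otherwise, against 190, and 181 with all 3 skins swapped and at most 1 otherwise, against 92. The 8 swaps for skin are too few for a share under 0.05, so with the pairs kept chance was left open for the comparison with odd-count livers, and the animal block gave 0 genes in edgeR (439 at an unadjusted p under 0.05, with 448 in DESeq2 without a block). For HC1 against LE, HC3 against LE and HC1 against HC3, the 10 splits are too few for a share under 0.05, with 645, 596 and 610 genes in the real split (1 split with a count as large, the real one, in each) and 0, 0 and 1 as the highest other.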

How the results depend on the processing

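The tests with library type as a term, without the 6 odd-count livers, with whole-table library sizes and with each table on its own were chosen after the data were seen, as were the gene list counts with the animal as a block, without those livers and in the tables with a pair. No gene named by rule reversed its sign under any alternative. Median-of-ratios scaling and whole-table library sizes left the calls of all 101 named genes, and DESeq2 those of 99. Library type as a term ended 5 of 101 calls, leaving out the odd-count livers 1 of 101, and testing the tables with a pair 3 of 41. With the animal as a block 27 of 41 calls of the tissue comparisons ended, and with the block and only the animals with both tissues all 41. Leaving out 1 intestine or skin ended 3 to 13 of 21, the most without the HC3 skin, while in the lineage comparisons leaving out 1 liver ended 2 of 10 without that of mms7722, 1 of 10 without that of mms7701, and 0 otherwise. No filter, the strict filter and the choice about symbols with several rows removed no gene from the tissue fits, so there they say nothing about stability. The length correction was not run.

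The count for intestine against liver moved from 190 to 380 with median-of-ratios scaling, 839 in DESeq2, 121 with library type as a term and 361 without the odd-count livers (179 of the 190 among them). Leaving out 1 intestine gave 82 (LE), 101 (UN), 103 (HC1), 123 (QU) or 133 (YA). HC1 on its own gave 374 genes, while edgeR on QU, UN or YA alone, with 1 residual degree of freedom and a single intestine assumed to vary like the livers, gave 0, with 898, 869 and 959 at an unadjusted p under 0.05. For skin against liver 92 became 176 with median-of-ratios scaling, 448 in DESeq2, 251 without the odd-count livers, 314 in the tables with a pair (more genes tested), 343 and 400 in HC1 and HC3 alone, and 0 in edgeR on UN alone (1028 at an unadjusted p under 0.05). Leaving out 1 skin gave 25 (HC3), 44 (UN) or 58 (HC1). The 1 gene of intestine against skin became 40 in DESeq2, 2 with library type as a term and 2 without the odd-count livers, and in edgeR 0 in the tables with a pair (137 at an unadjusted p under 0.05). It ranged from 0 to 1 as 1 library was left out, with 1 only without the YA intestine. No liver was left out on its own in these 3 comparisons. The cause of these shifts was not tested, apart from the numbers of genes and libraries.

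With the animal as a block, edgeR gave 99 genes for intestine, 0 for skin (439 at an unadjusted p under 0.05) and 0 for intestine against skin (29). With the block and only the animals with both tissues it gave 0, 0 and 0 (450, 285 and 137), where fewer libraries were fitted. DESeq2, without a block, gave 839, 448 and 40. Block and library type could not be separated, since every liver in a pair had odd low counts.

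Between livers, DESeq2 gave 1002, 996 and 977 genes for HC1 against LE, HC3 against LE and HC1 against HC3, and 1118, 1144 and 1112 for QU, UN and YA against H. leechii. Testing all genes of the tables compared gave 2229, 1775, 1904, 1048, 1231 and 1032, of more genes tested. Without the odd-count livers the counts were 1093, 1090, 1042, 1139, 1180 and 1203, and the cause was not tested. Library type as a term moved YA to 902. Leaving out 1 liver gave 432 to 562, 381 to 500, 410 to 509, 366 to 616, 383 to 678 and 354 to 575 genes in the same order, the lowest of the last 3 without the QU and UN livers of mms7722 and mms7712 and the YA liver of mms7701. Without the QU liver of mmsX002 it was 410. The F test gave 1158 to 1484 as 1 liver was left out and 1907 in DESeq2, within 1.5 times 1473.

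Of gene lists, 31 passed over all comparisons and 26 in those of tissues, and with an estimated correlation 7 and 7. In the tissue comparisons 20 passed with the animal as a block, 24 without the odd-count livers and 36 in the tables with a pair. Genes at 0 did not follow depth across library types, with 24.3% to 40.8% in the odd-count livers at 15103944 to 19281948 counts and 2.06% to 10.2% in the intestines at 1703075 to 3390245.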

Other observations

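No tests were run on the values of this part, which were picked after they were seen and are given as sums or shares over a library's whole table. The members of a list that a table holds differ between tables. Hepatocyte secreted proteins summed to 61469.8 to 251673 CPM in the 15 livers, with the highest value in the YA liver of mms7701, and to 208 to 17589 CPM in intestine. In skin they summed to 418 to 15686.5 CPM, the highest in the HC3 skin. Enterocyte and goblet cell markers summed to 7201 to 35319.9 CPM in intestine and 182 to 10273 CPM in liver. Keratinocyte markers reached 27574 CPM in the HC1 intestine, against 2446 to 5259 CPM in the other 4 intestines. Skeletal muscle markers summed to 11484 to 15989 CPM in the 3 skins and 6.66 to 4894 CPM in liver, and smooth muscle markers to 2279 to 8282 CPM in intestine.

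Single animals stood out in several groups. The LE liver of mms7730 had 2099.6 CPM of interferon response genes, against 188 and 196 CPM in the other LE livers, with ISG15 at 1178 CPM, and its intestine had 4612 CPM, with IFIT5 at 4093 CPM. IFIT5 was also at 2278 CPM in the YA intestine. In the HC1 liver of mms7666, yolk and egg proteins summed to 4902 CPM, against 1201 and 717 CPM in the other HC1 livers, with the egg envelope gene ZP4 at 2807 CPM. The same liver had 2359 CPM of cell cycle genes, against 273 and 158 CPM, with CCNB2 at 1468 CPM. The endothelial receptor STAB2 stood at 9311 CPM in the QU liver of mmsX002 and 1636 CPM in that of mms7722. The pepsinogen gene PGA3 was at 1229 CPM in the UN liver of mms7714. Heat shock genes summed to 160480 CPM in the UN liver of mms7712 and 143725 CPM in its intestine, against 32684.5 CPM in the UN liver of mms7714. In the liver of mms7712 DNAJA1 alone was at 152088 CPM, and in its intestine PDIA3 was at 76991 CPM and HSPA8 at 57740.1 CPM. Complement summed to 76159.6 CPM in the YA liver of mms7700 and 37979.9 CPM in that of mms7701.

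In each table a few genes took a large share of the counts. PTPN3 made up 24.3% and 24.7% of the QU livers, F2 14.0% and 19.6% of the YA livers, and DNAJA1 15.2% of the UN liver of mms7712. MT-ND5 took 10.2% to 14.3% of the HC3 livers, AFM 8.96% to 13.0% of the HC1 livers and FGB 9.11% of the LE liver of mms7730. In intestine the highest shares were PTPN3 at 18.7% in QU, CLTC at 14.1% in YA, RPL27A at 10.2% in UN and SIAE at 7.41% in LE, and the chitinase gene CHIT1 led in HC1.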
